A study of Mus musculus with 4 samples.

How the data were processed

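The series holds RNA sequencing of the stromal vascular fraction, the non-adipocyte cells released from fat tissue, of mouse inguinal white adipose tissue. The labels name 4 libraries from wild-type males at postnatal day 21, and each library is a pool of 3 mice. They form a design of 2 parental groups by 2 drinks. LnF1 and ObF1 are the labels' names for the offspring groups, in a series whose title concerns obesity of the parents, and the drinks are water and 1,3BD, as the labels write it. With 1 library per combination, no combination has replicates. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a KAPA mRNA kit. The submitters' processing notes name the mm10 build, edgeR and DESeq2 without role or version. The aligner, the counter and the annotation release are not given in the sources used here, nor is the use of strand, so antisense and overlapping genes could not be separated by it.

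The deposited table is named as raw counts, but its values are not whole numbers. It holds a scaled signal per gene: every deposited value was a whole multiple of the smallest value in its column, so that 100% of values came out as whole reads within a relative tolerance of 1e-06. The factors implied by the column totals were 0.950 for LnF1 water, 1.134 for LnF1 1,3BD, 0.885 for ObF1 water and 1.05 for ObF1 1,3BD. Their product was 1.00, as for edgeR factors of any method, so the method that gave them was not identified. The unit was therefore CPM, reads scaled to the library total times its scaling factor. The recovered depth was 24804006, 24586827, 26000090 and 25432747 reads in the same order, so that 1 read was worth between 0.0359 and 0.0435 CPM. A count of 0 allows up to 3 reads, which is between 0.108 and 0.130 CPM. These limits cover counting error only, and none covers the spread between animals.

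The table had 55536 rows, of which 28572 had 0 reads in all 4 libraries. Of 2339 rows without a symbol, 2271 were named from the reference gene table, and 99.85% of identifiers were found there. Rows whose symbol repeated that of a row with more reads (126) kept their identifier in the name. Gene coordinates are those of the GRCm38 (mm10) annotation supplied with the reference genome. Columns were matched to samples by name, with the 2 columns that name no drink matched to water.

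The design had been fixed for raw counts, with an edgeR quasi-likelihood test. Because the deposited values were scaled, the main test was limma on log2(CPM + 0.0796), a pseudocount worth 2 reads, with a mean-variance trend and robust empirical Bayes moderation. Fold changes on this scale understate the change of genes with few reads. Genes with at least 1 CPM in at least 2 libraries entered (12838). The model was additive in drink and parents and left 1 residual degree of freedom, in which the spread is the failure of a difference to repeat in the other drink or the other parental group. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The edgeR count test on the recovered reads, added after the unit was known, called 19 genes higher and 13 lower for parents, and 2649 higher and 2884 lower for drink. Differences between single libraries carry no p-value and were counted by size, at least 1 on the log2 scale at a mean CPM of at least 5.

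Gene lists (54) were fixed before the data were examined, and the 43 with at least 3 tested members entered, on the same log2 values, camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. With 1 residual degree of freedom, the correlation between genes can hardly be estimated. Camera with an estimated correlation thus had little power, and a list that failed it is not thereby argued against. Camera with a preset correlation takes genes as its units and does not measure the spread between animals. For each single-library difference, the list median was placed among 10000 random lists matched on mean expression. Genes are named by a rule fixed before the data were examined. In each main comparison these are the 12 genes per direction with the largest smaller difference among genes at a mean CPM of at least 5 that moved the same way in both single-library differences. For the reversal they are 6 per direction. Up to 4 members per list described and a fixed set of adipose, ketone and sex-linked genes were added. Gene models named only by a number were skipped, as were names that end in Rik, a pattern that 9930111J21Rik2 escapes. A few genes that the rule names are not reported here. Genes outside the rule are marked as chosen after their values were seen.

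The test was tested on simulated data with 200 of 12838 genes changed. For parents it recovered 54.9% of genes changed by 1 on the log2 scale and 100% of those changed by 2 or 3, with 11 false calls. For drink it recovered 64.1% and 100%, with 6 false calls. The simulated genes were independent, took their spread from the trend with expression and held no second effect. Only genes at a mean CPM of at least 5 were changed. These rates therefore describe the test on such counts, and not its power or false calls with real pools of mice. Alternatives were edgeR, DESeq2 and limma voom on the recovered reads, other scalings, filters and pseudocounts, no covariate, each library left out, summed symbols, and removal of ribosomal and mitochondrial genes or of a length and GC trend. The software was R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.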

Results

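Gene expression was measured in 4 libraries of the stromal vascular fraction of inguinal white fat from male mice at postnatal day 21, each a pool of 3 mice. There was 1 library for each combination of parents (LnF1 or ObF1) and drink (water or 1,3BD), with 24804006 recovered reads for LnF1 water, 24586827 for LnF1 1,3BD, 26000090 for ObF1 water and 25432747 for ObF1 1,3BD. No value below has a replicate within its group. The error of a difference rests on how far differences failed to repeat in the other drink or the other parental group. It is moderated toward that of other genes with similar expression, so it is not the failure to repeat of the named gene alone. Values are scaled CPM, and log2 differences come from limma with their standard error (SE).

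Core markers of blood, endothelial, epithelial, muscle and mature fat cells were absent or nearly so, while fibroblast genes were abundant. Pdgfra, a marker of adipose progenitors, stood at 243, 281, 236 and 412 CPM in LnF1 water, LnF1 1,3BD, ObF1 water and ObF1 1,3BD. The smooth muscle actin gene Acta2 reached 7692 and 8097 CPM in the water libraries. Ptprc, carried by all white blood cells, never exceeded 0.150 CPM, and Adgre1 of macrophages reached 0.807 CPM in LnF1 water. Cd3e, Cd79b, Hbb-bs, Epcam and Adipoq had 0 reads in every library, which allows at most 0.130 CPM, and Cldn5 of endothelial cells had at most 1 read. Ucp1, the uncoupling protein of brown and beige fat, also had 0 reads. The Y-linked genes Ddx3y (88.9 to 140.5 CPM), Kdm5d (26.5 to 46.7), Uty (21.4 to 45.9) and Eif2s3y (38.3 to 85.5) were present in all 4 libraries, while Xist had at most 7 reads, as in males.

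The first comparison asked how offspring of the 2 parental groups differ. Pgr, Greb1 and Dkk2 were higher in ObF1 in both drinks, and Fbn2 and Cebpa lower. Pgr, the progesterone receptor (chromosome 9, 8899833 to 8968611, plus strand, mm10), rose from 1.87 to 17.0 CPM in water and from 0.825 to 10.1 CPM in 1,3BD, a log2 difference of 3.31 (SE 0.34, limma adjusted p = 0.00141). Greb1, an estrogen-responsive gene, rose 7.22-fold, and Dkk2, a secreted Wnt inhibitor, rose 6.83-fold, from 20.3 to 147 CPM in water. Fbn2, which encodes the matrix protein fibrillin 2 (chromosome 18, 58008623 to 58210487, minus strand), fell from 416 to 81.3 CPM in water and from 60.4 to 13.3 CPM in 1,3BD. Cebpa, a transcription factor of adipocyte differentiation, was the 1 of 22 adipogenic transcription factor genes that passed, in a list that was not called (camera adjusted p = 0.0662, 2 higher and 3 lower adjusted over the list alone) but was called lower without a filter and at a mean CPM of at least 5, and fell by 1.39 on the log2 scale (SE 0.22, limma adjusted p = 0.0283), from 43.7 to 17.9 CPM in water and from 51.5 to 18.1 CPM in 1,3BD.

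Of 12838 genes tested, 25 were higher and 13 lower in ObF1. Among the 12 highest by rule, 10 passed. They included Mmp3, a matrix metalloprotease (log2 3.40), Adcyap1r1, the receptor of the neuropeptide PACAP (2.48), Crispld2 (2.30), Aldh1a2, a retinoic acid synthesis enzyme (2.19), and Ampd3, an AMP deaminase (2.13). Ctgf, a matricellular growth factor gene (1.78), and H2-Ab1, a class II antigen presentation gene (2.38 to 11.6 CPM in water and 6.63 to 22.6 CPM in 1,3BD), passed as well. Lmcd1 (2.11, limma adjusted p = 0.0581) and 9930111J21Rik2 (1.95, limma adjusted p = 0.0668) did not pass. Among the 12 lowest by rule, 8 passed: Syt13 (-2.94), Fbn2 (-2.26), Nov, a matricellular gene (-2.20), Itm2a (-1.98), Cpz (-1.66), Bmf, a pro-apoptotic gene (-1.60), Tnxb (-1.49) and Pltp (-1.43). Plagl1 (-3.04, limma adjusted p = 0.212), Gdf10 (-2.87, limma adjusted p = 0.140), Tnmd (-1.71, limma adjusted p = 0.0506) and Wnt4 (-1.55, limma adjusted p = 0.0715) did not. All the named genes that fell short in either direction passed with DESeq2, which called more genes. Lmcd1 and Tnmd also passed in edgeR and limma voom, while edgeR left 2 named genes short, Bmf among them. The chemokine gene Cxcl14 (2.27) and Ptgs2, the inducible cyclooxygenase (1.82), also rose. Chosen after their values were seen, Lgr6 (0.849 to 13.8 CPM in water) was among the other genes that rose, and Tril (-2.68) among those that fell. 1500015O10Rik, which the rule skips for its name, fell too (-3.01, limma adjusted p = 0.00141), from 79.5 to 8.17 CPM in water. By size it would have ranked above Nov, the first of the 12 lowest.

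Imprinted growth genes, expressed from 1 parental allele, were lower in ObF1 as a list. Of 20 members tested, 0 passed over all genes, and 7 were lower adjusted over the list alone, with 0 higher. Plagl1 passed over all genes with DESeq2, with robust moderation off, without a filter, and in edgeR with robust off. The list median was -0.79, with -1.08 in water (percentile 0 among random lists) and -0.47 in 1,3BD (percentile 0.01). Camera gave an adjusted p of 2.52e-09 with the preset correlation. That test takes genes as its units, so its p is too small if the members move together more than was preset. Fry did not call the list (fry adjusted p = 0.677). The list was not called with an estimated correlation (camera adjusted p = 0.767 with an estimated correlation), a test with little power here. Plagl1, a growth-regulating zinc finger gene (chromosome 10, 13060504 to 13131694, plus strand), stood at 99.1 against 5.65 CPM in water and 58.1 against 14.8 CPM in 1,3BD. H19, a non-coding RNA, stood at 250.3 against 14.3 CPM in water and 13.1 against 5.17 CPM in 1,3BD, and Dlk1, a preadipocyte gene, at 13.8 against 1.91 CPM and 8.61 against 5.55 CPM. Gnas gave a log2 difference of -1.69 (limma adjusted p = 0.0686).

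**Figure D1:**
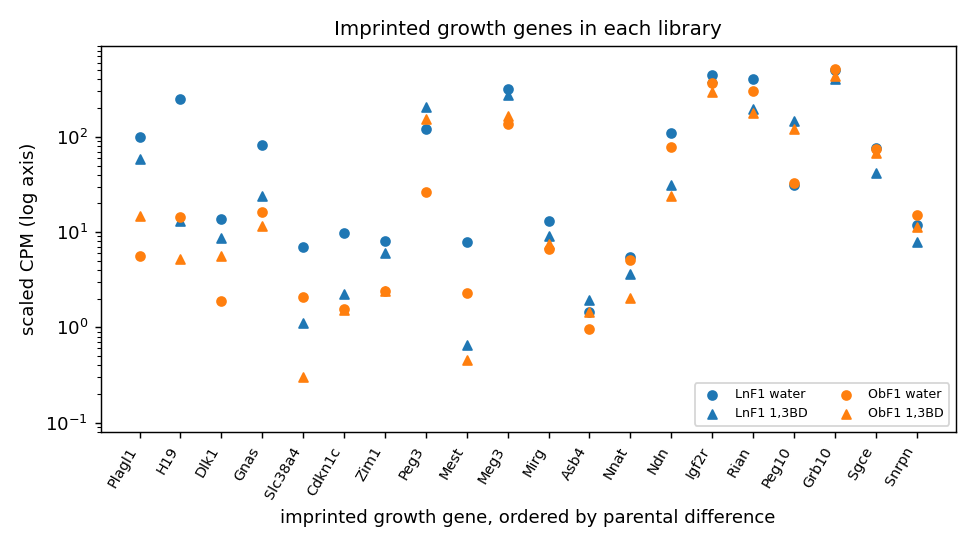
Scaled CPM (log axis) of the 20 tested imprinted growth genes in each of the 4 libraries, ordered by the parental difference. Circles are water and triangles 1,3BD, blue LnF1 and orange ObF1, and Plagl1 runs from 99.1 CPM in LnF1 water to 5.65 CPM in ObF1 water.

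Of the 43 lists, 2 were called higher and 6 lower in ObF1 by camera, and 0 were called with an estimated correlation (lowest adjusted p = 0.767 with an estimated correlation) or by fry (lowest adjusted p = 0.509). Nuclear genes of oxidative phosphorylation had a median of -0.19 (68 members, camera adjusted p = 0.000733, adjusted p = 0.767 with an estimated correlation), ribosomal proteins -0.14 (73 members, camera adjusted p = 0.00261, adjusted p = 0.767 with an estimated correlation) and cholesterol synthesis -0.23 (24 members, camera adjusted p = 0.00961, adjusted p = 0.767 with an estimated correlation). Histone deacetylases and sirtuins had -0.18 (18 members, camera adjusted p = 0.0397, adjusted p = 0.767 with an estimated correlation) and fatty acid oxidation -0.14 (23 members, camera adjusted p = 0.0460, adjusted p = 0.767 with an estimated correlation), a call that ended with RLE scaling. Mitochondrially encoded genes had a median of 0.63 (14 members, camera adjusted p = 3.66e-05, adjusted p = 0.767 with an estimated correlation), and glycolysis and hypoxia genes 0.16 (25 members, camera adjusted p = 0.00261, adjusted p = 0.767 with an estimated correlation). The medians differed between drinks, untested. They were -0.33 in water and -0.0322 in 1,3BD for oxidative phosphorylation, -0.305 and 0.0302 for ribosomal proteins, and -0.23 and 0.0226 for fatty acid oxidation. Mitochondrially encoded genes had 0.13 and 1.06, and glycolysis and hypoxia genes 0.27 and 0.0990. Percentiles among random lists, water first, were 0 and 10.5 for oxidative phosphorylation, 0 and 4.05 for ribosomal proteins, and 0.01 and 0.05 for cholesterol synthesis. They were 6.44 and 7.97 for histone deacetylases and sirtuins, and 0.05 and 43.2 for fatty acid oxidation. Mitochondrially encoded genes lay at 71.5 and 100, and glycolysis and hypoxia genes at 99.5 and 46.7. In these 7 lists 0 members passed over all genes, and adjusted over the list alone 1 ribosomal protein gene was lower and 3 glycolysis and hypoxia genes were higher. The share of reads from mitochondrial genes was 1.128% and 1.30% in the LnF1 and ObF1 water libraries and 2.78% and 5.80% in the 1,3BD libraries. Some mitochondrial genes share reads with near-identical nuclear copies and are uncertain.

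The parental calls rest on the additive fit. Without the drink covariate, 0 genes passed (39 at an unadjusted p under 0.05 in limma, against 1392 in the additive fit), and fits that left out 1 library, which must also drop this covariate, called 0 higher, with 2 lower without LnF1 1,3BD, 1 lower without ObF1 water and 0 lower without either other library. DESeq2 called 69 higher and 48 lower, edgeR 19 and 13, and library totals without factors, which shift the median gene by -0.11 on the log2 scale, changed the split from 25 and 13 to 16 and 13. Removing a length and GC trend kept 19 of the 25 higher and 6 of the 13 lower, and left 4 named genes short of the threshold at log2 differences of -1.48 for Bmf (SE 0.25, before -1.60 with SE 0.28), -1.34 for Cpz (SE 0.27, before -1.66 with SE 0.28), -1.16 for Tnxb (SE 0.24, before -1.49 with SE 0.24) and -1.17 for Pltp (SE 0.22, before -1.43 with SE 0.25).

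**Figure D2:**
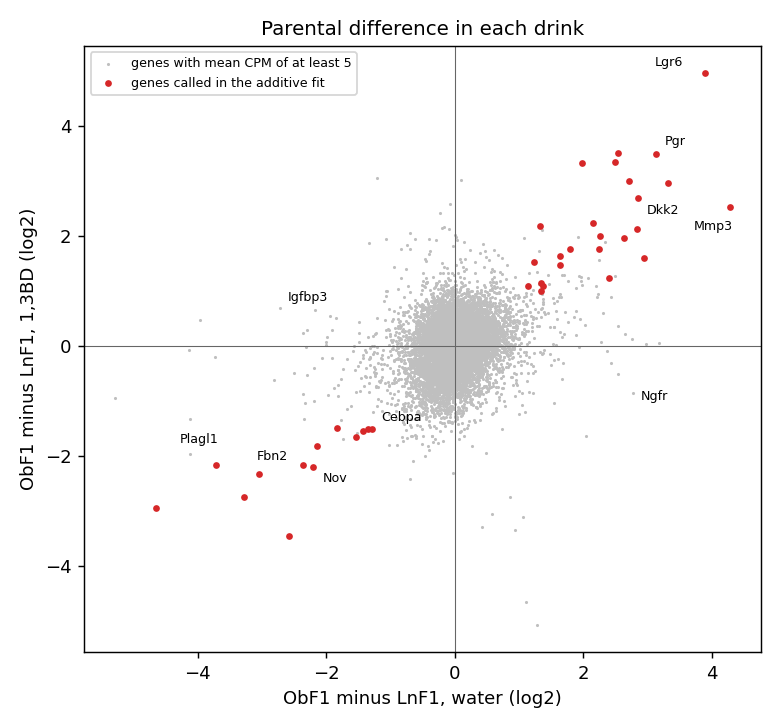
Parental difference (ObF1 minus LnF1, log2) in water on the x axis and in 1,3BD on the y axis, 1 point per gene, with grey points for genes at a mean CPM of at least 5 and red points for the 38 genes called. Pgr lies at 3.13 and 3.49, and Ngfr at 2.78 and -0.86.

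The parental difference was also set side by side in each drink, 2 differences that share no library. Across 10238 genes its correlation was 0.279 (Spearman's rho 0.258), where 20 simulations without an effect gave at most 0.0154, and 59.6% of genes had the same sign. Genes are not independent replicates. The simulations held independent noise and no drink effect, so their low correlation was fixed in advance. They show only that such noise does not give the observed value, and other differences between the pools were not tested. In both drinks, 45 genes were at least 2-fold higher in ObF1, against 3.49 for independent lists, and 28 were at least 2-fold lower, against 4.32, while 11 were 2-fold different in opposite directions. The robust SD across genes was 0.319 for the parental contrast, 0.241 for the interaction contrast and 0.837 for the drink contrast.

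The second comparison asked how 1,3BD differs from water. Zbtb16, Fabp4 and Pparg were higher with 1,3BD in both parental groups, and Acta2 lower. Zbtb16, a zinc finger transcription factor gene (chromosome 9, 48654297 to 48836222, minus strand), had 0 reads in both water libraries and 48.7 and 39.8 CPM in LnF1 and ObF1 with 1,3BD, at least 382-fold and 305-fold higher against a floor of 3 reads per library. Fabp4, the fatty acid binding protein of adipocytes, rose from 5.94 to 223 CPM in LnF1 and from 8.47 to 151 CPM in ObF1, and Pparg, the master regulator of adipogenesis, rose by a log2 difference of 1.42 (SE 0.28, limma adjusted p = 0.00201). The list of adipogenic transcription factors was split, with 3 of 22 higher, 3 lower and 16 not passed. It was not called (camera adjusted p = 0.801). Acta2 (chromosome 19, 34241090 to 34255590, minus strand) fell from 7692 to 113 CPM in LnF1 and from 8097 to 165 CPM in ObF1. Of 12838 genes, 2466 were higher and 3189 lower with 1,3BD, and 1311 and 2103 of them by at least 2-fold.

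All 24 genes named by rule for this comparison passed. Prg4, a lubricating proteoglycan gene (log2 6.96), the metallothionein gene Mt2 (5.48), Rgs2 (4.81), Gclc, a glutathione synthesis gene (4.36), Gda (4.01), Draxin (3.97) and the alkaline phosphatase gene Alpl (4.10) rose. So did Map7d2, from 0.0425 to 7.21 CPM in LnF1 and 0.434 to 17.0 CPM in ObF1, and Tmem100, from 0.976 to 19.6 CPM in LnF1 and 0 to 17.1 CPM in ObF1. Prl2c3 (4.68) belongs to a family of near-identical genes and is uncertain. Nov (-7.09), the hyaluronan-degrading gene Cemip (-7.73), Ctgf (-6.10), Mrvi1 (-5.99), Col8a1, a collagen gene (-5.76), Lrrc15 (-5.88) and Lmod1 (-5.60) fell, and so did Gjb2 (24.4 to 0.108 CPM in LnF1), C1qtnf2 (9.93 to 0.108 CPM in LnF1), Ptprb (19.3 to 0.113 CPM in ObF1) and Serpinb9b (20.9 to 0.188 CPM in ObF1), which has near-identical relatives. Both Gjb2 and C1qtnf2 had 0 reads in ObF1 1,3BD.

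Glucocorticoid-responsive genes rose in 11 of 14 and fell in 2 (11 and 2 adjusted over the list alone), with a median of 1.86 in LnF1 and 1.36 in ObF1 (camera adjusted p = 1.92e-05, adjusted p = 0.712 with an estimated correlation). They included Mt1 (4.16), Pdk4, which restrains glucose oxidation (2.53), Klf9 (2.30) and Fkbp5 (1.98). Of 22 NRF2 antioxidant genes, 12 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.712 with an estimated correlation). The cystine transporter gene Slc7a11 rose by a log2 difference of 3.38 and Hmox1 from 295 to 731 CPM in LnF1 and 172 to 1113 CPM in ObF1, while Gpx1 fell by 2.45 on the log2 scale. Endoplasmic reticulum stress genes rose in 13 of 22 and fell in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.00467, adjusted p = 0.712 with an estimated correlation), with Dnajb9 at 2.47 and the chaperone gene Hspa5 at 1.45. Of 10 mature adipocyte genes tested, 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.712 with an estimated correlation), among them Tusc5 (2.78) and the lipase gene Lipe (1.02), a call that ended with library totals. Mitochondrially encoded genes rose in 10 of 14 (11 adjusted over the list alone, camera adjusted p = 0.000509, adjusted p = 0.712 with an estimated correlation), with mt-Co1 at 1.74.

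Interferon-stimulated genes fell in 30 of 30 (30 adjusted over the list alone), with a median of -2.68 and a camera adjusted p of 2.54e-13 (adjusted p = 0.712 with an estimated correlation). The log2 difference was -4.90 for Ifit3, -3.95 for Isg15, -3.93 for Gbp2 and -3.89 for Irgm1. Extracellular matrix and fibrosis genes fell in 24 of 33 (26 adjusted over the list alone, camera adjusted p = 3.52e-10, adjusted p = 0.712 with an estimated correlation), with Col14a1 at -4.76. Mural cell genes, which stand for contractile cells of vessels and also for myofibroblasts, fell in 11 of 14 (12 adjusted over the list alone, camera adjusted p = 1.19e-08, adjusted p = 0.712 with an estimated correlation), with a median of -4.19, Myl9 at -5.34 and Cnn1 at -4.97. Nuclear oxidative phosphorylation genes fell in 37 of 68 and rose in 1 (38 and 1 adjusted over the list alone, camera adjusted p = 4.06e-05, adjusted p = 0.712 with an estimated correlation), with Ndufb7 at -1.70 and Atp5d at -1.52. Immediate early genes fell in 17 of 24 and rose in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 0.000493, adjusted p = 0.712 with an estimated correlation), with Klf2 at -3.92 and Cyr61 at -3.15. Vascular endothelial genes fell in 8 of 9 and rose in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00568, adjusted p = 0.712 with an estimated correlation), with Tek at -2.48, a call that ended at a mean CPM of at least 5.

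Further lists were called lower in the same test. Glycolysis and hypoxia genes fell in 12 of 25 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00569, adjusted p = 0.712 with an estimated correlation), with Eno1 at -1.76 and Ldha at -1.52. Pan-progenitor genes fell in 10 of 18 (10 adjusted over the list alone, camera adjusted p = 0.00960, adjusted p = 0.712 with an estimated correlation), with Cd9 at -2.93 and Thy1 at -1.73. Ribosomal protein genes fell in 23 of 73 (17 adjusted over the list alone, camera adjusted p = 0.00415, adjusted p = 0.712 with an estimated correlation), with Rps14 at -1.41. The list median was -0.57 in LnF1 (percentile 1.77 among random lists) but -0.16 in ObF1 (percentile 84.2). In ObF1 the list thus did not lie below matched lists. Nuclear ribosomal RNA took 2.07%, 1.90%, 2.59% and 0.179% of reads in LnF1 water, LnF1 1,3BD, ObF1 water and ObF1 1,3BD. The ObF1 1,3BD library thus had the lowest such share, and it also had the highest share of mitochondrial reads (5.80%). It enters the parental difference in 1,3BD and the drink difference in ObF1, and whether its preparation differed was not tested. Cell cycle genes fell in 13 of 26 (13 adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.712 with an estimated correlation), with Cdc20 at -2.09. DNA replication genes fell in 14 of 26 and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 0.0150, adjusted p = 0.712 with an estimated correlation), with Mcm6 at -1.44 and Rrm2 at 1.37. NF-kB genes fell in 10 of 18 and rose in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.712 with an estimated correlation), with Ccl2 at -3.09. Schwann cell and nerve genes fell in 8 of 12 (9 adjusted over the list alone, camera adjusted p = 0.000509, adjusted p = 0.712 with an estimated correlation), with Cnp at -2.62. Skeletal muscle genes fell in 4 of 6 (4 adjusted over the list alone, camera adjusted p = 0.0450, adjusted p = 0.712 with an estimated correlation) and core histones in 8 of 11 (8 adjusted over the list alone, camera adjusted p = 0.0216, adjusted p = 0.712 with an estimated correlation), the latter a call that ended at a mean CPM of at least 5. The core markers Ckm of muscle and Cldn5 of endothelial cells had at most 1 read in any library. Falls in the skeletal muscle and vascular endothelial lists thus need not be changes of such cells. No core marker of Schwann cells was checked. With an estimated correlation, 0 of the 5 higher and 15 lower lists were called (lowest adjusted p = 0.712 with an estimated correlation), and fry called 0 (lowest adjusted p = 0.162).

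**Figure D3:**
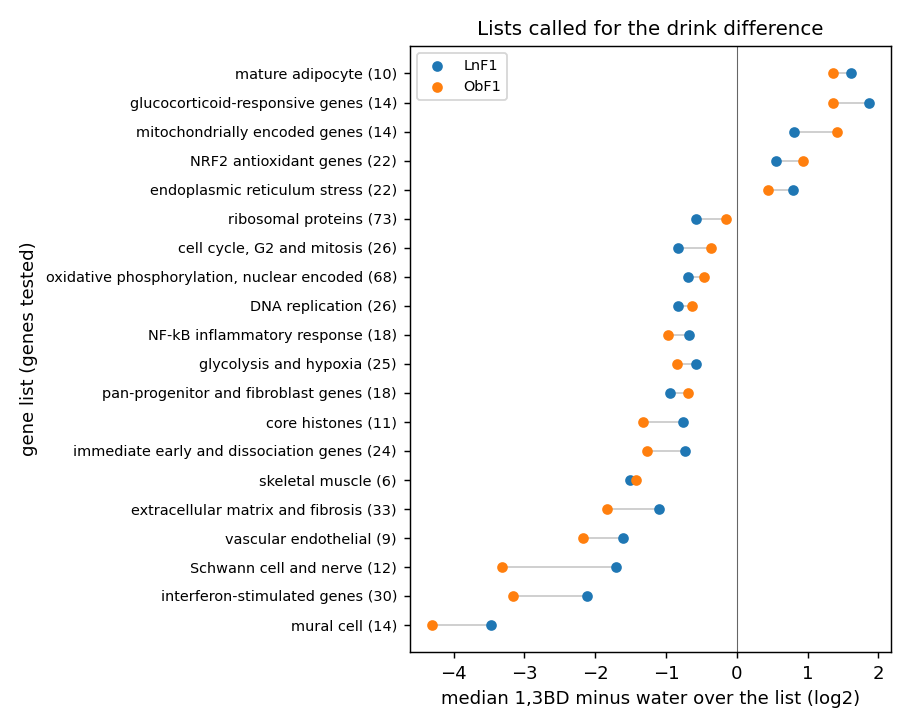
Median log2 difference (1,3BD minus water) of each of the 20 called lists, with blue points for LnF1, orange points for ObF1 and the number of tested genes in brackets. The mural cell list lies at -3.48 and -4.31, and the glucocorticoid list at 1.86 and 1.36.

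Ketone body genes were not called as a list (camera adjusted p = 0.543), with 2 of 11 higher and 5 lower (2 and 6 adjusted over the list alone). The monocarboxylate transporter genes Slc16a1 (log2 2.63) and Slc16a6 (2.57) rose. Oxct1, the enzyme that activates acetoacetate, fell by 0.76 (SE 0.20, limma adjusted p = 0.00928), and Bdh1, which interconverts ketone bodies, fell by 0.95 (SE 0.32, limma adjusted p = 0.0320). Ppargc1a stood at 0.0424, 0.143, 0.0869 and 0.975 CPM and was not tested. Prdm16 gave -0.44 (limma adjusted p = 0.326) and Pdgfra 0.51 (limma adjusted p = 0.0742).

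The drink difference repeated across parental groups, with a correlation of 0.866 across 10238 genes (Spearman's rho 0.830), and 606 genes were at least 2-fold higher and 1113 at least 2-fold lower in both groups. The split of calls moved with scaling, to 3117 higher and 2686 lower with upper quartile factors and 3663 and 2283 with library totals, which shift the median gene by 0.13 and 0.25 on the log2 scale. Removing a length and GC trend kept 1382 of the 2466 higher and 2199 of the 3189 lower. Without the parental covariate the counts were 1866 and 2522, and fits that also left out LnF1 water, ObF1 water or ObF1 1,3BD gave 668 and 1232, 817 and 1326, and 1004 and 1739.

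The third comparison asked whether 1,3BD opposed the parental difference. Genes higher in ObF1 than LnF1 with water, and lower with 1,3BD than water in ObF1, included Rgs8 (1.995, 18.7 and 0.150 CPM in LnF1 water, ObF1 water and ObF1 1,3BD), Rap1gap2 (2.504, 20.3 and 1.43 CPM), Cxcl14 (39.6, 307 and 16.0 CPM), Dkk2 (20.3, 147 and 4.84 CPM), the neurotrophin receptor gene Ngfr (8.57, 59.5 and 0.675 CPM) and Cadm4 (2.38, 16.6 and 0.863 CPM). The opposite course was seen for Scara5 (11.5, 0.217 and 8.77 CPM), Tmem100 (0.976, 0 and 17.1 CPM), Gdf10 (19.4, 1.17 and 12.4 CPM), Igfbp3 (403, 61.4 and 344 CPM), Gas1 (165, 33.1 and 169 CPM) and the imprinted gene Peg3 (122, 26.5 and 155 CPM). Of both sets, only Cxcl14 and Dkk2 passed the limma test for parents. Ngfr, Scara5, Igfbp3 and Gas1 passed neither for parents nor for drink. In LnF1 all 6 of the first set were also lower with 1,3BD than with water, at 0.143 CPM for Rgs8, 1.40 for Rap1gap2, 5.27 for Cxcl14, 0.681 for Dkk2, 1.29 for Ngfr and 0.789 for Cadm4. Of the second set, Igfbp3 was lower with 1,3BD in LnF1 (213 CPM) and the other 5 were higher. Both differences use the ObF1 water library, which by itself gives a negative correlation. Across genes the correlation was -0.113 and the covariance -0.0578, where 20 simulations without an effect gave -0.501 and -0.0765 on average. The simulations held no drink effect either. That effect widens the observed differences and weakens their correlation, so the correlations cannot be compared. The covariance turned with the expression floor: at a mean CPM of at least 20 it was -0.0326, where the simulations gave -0.0672 to -0.0602, but at a mean CPM of at least 1 it was -0.136, where they gave -0.101 to -0.0937. The correlation was -0.0791 and -0.195 at these floors, where the simulations gave -0.499 and -0.500 on average, values that cannot be compared for the same reason. Whether 1,3BD opposed the parental difference across genes was therefore not settled.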

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

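The tests on other cell types, glucocorticoid exposure, culture, depth and dividing cells were chosen only after the result was seen, and the removal of ribosomal and mitochondrial genes and of a length and GC trend were settings added after the data were seen. Results are listed here because the parental or drink difference had opposite signs in the 2 drinks or the 2 parental groups. In every case the difference was not tested, since each combination has 1 library, and opposite signs are common where there is little difference: 20 of 43 lists and 5 of 17 genes for parents, and 1 of 43 lists and 1 of 17 genes for drink.

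The list of Schwann cell and nerve genes had a parental median of 1.97 in water and -0.46 in 1,3BD, and its member Ngfr 2.78 and -0.86. Igfbp3 gave -2.71 and 0.69 for parents, and -0.92 in LnF1 and 2.48 in ObF1 for drink. Other lists with opposite parental medians, water first and 1,3BD after it, were vascular endothelial (0.85 and -0.0478), complement (-0.11 and 0.74), interferon-stimulated (0.13 and -0.51), macrophage (-0.28 and 0.49), mural cell (0.45 and -0.17), CD142 stromal (-0.42 and 0.13), endoplasmic reticulum stress (0.39 and -0.0462) and committed preadipocyte genes (0.30 and -0.37). Committed preadipocyte genes also differed for drink, with 0.14 in LnF1 and -0.54 in ObF1.

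Smaller opposite medians for parents were those of cell cycle (-0.33 and 0.0121), ribosomal protein (-0.305 and 0.0302), extracellular matrix (0.23 and -0.16), NF-kB (0.23 and -0.14), fatty acid oxidation (-0.23 and 0.0226), NRF2 (-0.16 and 0.23), DNA replication (-0.15 and 0.0051), class II antigen presentation (0.16 and -0.0077), tricarboxylic acid cycle (-0.11 and 0.0410), histone acyltransferase (-0.0254 and 0.30) and lipogenesis genes (0.0624 and -0.0037). Pdgfra gave -0.0441 and 0.55, Prdm16 0.45 and -0.15, and Bdh1 0.14 and -0.33.

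The drink labels separate 5655 called genes. After ribosomal RNA and mitochondrial genes were removed, 99.9% of the called genes were called in the same direction. This removal shifted the median drink difference by only 0.0011 on the log2 scale. Such near-complete retention was thus fixed in advance and does not test their share of reads as the cause. Core markers of other cell types reached at most 0.188 CPM in the 1,3BD libraries, which argues against added cells of those types. After a length and GC trend was removed, 63.4% were still called in the same direction, so a part of the calls cannot be told apart from such a trend, which real differences could also follow. Glucocorticoid exposure of the 1,3BD cells may contribute, since the lower of the 2 list medians was 1.36, and an effect of the drink itself stays open and untested, as does any unlabelled difference in handling that went with the drink.

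Blood and immune cell RNA was nearly absent from a fraction that usually holds such cells. The smallest library had 24.6 M reads, which argues against too few reads. Growth in culture before RNA extraction is a candidate explanation for the water libraries, where Acta2 and Thbs1 were at 7692 CPM or more. In the 1,3BD libraries, where the same RNA was nearly absent, Acta2 was at 113 CPM in LnF1, so the test did not decide there. The labels name no culture step, and a sort or depletion of blood cells was not tested.

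Imprinted growth genes were called lower in ObF1 as a list by camera with the preset correlation, with 0 of 20 members passing (Plagl1 did in DESeq2 and 3 other settings). Fry did not call the list (fry adjusted p = 0.677). The list was not called with an estimated correlation (camera adjusted p = 0.767 with an estimated correlation), a test with little power here. The list median stayed at -0.76 or below under every scaling tried. Those scalings shift the median gene by only -0.11 to 0.034 on the log2 scale. This outcome was thus nearly fixed in advance and does not test scaling as the cause. In 1,3BD the cell cycle list had a median of 0.0121, with 13 of 26 genes lower, and the imprinted list -0.47, a gap of 0.48. The SD of 0.37 over the cell cycle genes is scatter within 1 pair of libraries and not the error of this gap. The cell cycle list thus showed no fall there, but fewer dividing cells were not excluded. In water the cell cycle list was lower too, with a median of -0.33 and 24 of 26 genes lower where the imprinted list was at -1.08, so fewer dividing cells may contribute there. The parents, and differences between single pools of 3 mice, stay open and untested.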

How the results depend on the processing

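Settings chosen after seeing the data were edgeR with the planned TMM scaling or robust off, other pseudocounts, other scalings within limma, library totals, simulations of the reversal at other floors, removal of ribosomal and mitochondrial genes, and the length and GC correction. For the changes below the cause was not tested, except that fewer libraries or genes enter some settings. For parents (25 genes higher, 13 lower), the counts became 69 and 48 with DESeq2, 196 and 156 without a filter, 10 and 5 at a mean CPM of at least 5, 8 and 5 with a pseudocount of 1 CPM, and 0 and 0 without covariate, and library totals gave 16 higher. Fits that leave out 1 library also drop the covariate. They gave 0 to 0 higher and 0 to 2 lower, the lone library being assumed to vary like the others. For drink, they gave 668 to 1926 higher and 1232 to 2731 lower, and every other setting stayed within 1.5 times of 2466 and 3189. DESeq2 kept all 38 parental calls, edgeR 29 of them. For drink, similar counts can hide a change of genes. With the length and GC trend removed, only 56.0% of the higher and 69.0% of the lower calls were kept. Over all settings, values of named genes kept their direction and side of the threshold in 1144 cases, fell short of it in 127, newly passed it in 42 and turned in 19.

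Leaving out 1 library without covariate mixes the drink into the parental difference and turned 11 named genes, none of them past the threshold when turned. The ranges of the parental log2 difference were -0.27 to 4.65 for Aldh1a2, -0.38 to 4.28 for 9930111J21Rik2, -0.41 to 4.64 for Lmcd1, -1.28 to 4.84 for Ctgf, -5.75 to 1.34 for Nov, -3.66 to 0.24 for Tnmd, -1.54 to 0.30 for Pparg, -0.15 to 0.66 for Pdgfra, -0.22 to 0.52 for Prdm16, -0.68 to 0.50 for Bdh1 and -0.29 to 0.61 for Oxct1.

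With mean CPM floors of 1 and 20, the correlation of the drink difference between parental groups was 0.843 and 0.876, that of the reversal -0.195 and -0.0791, and the robust SDs were 0.347 and 0.287 for parents, 0.898 and 0.797 for drink and 0.269 and 0.223 for the interaction. Camera with an estimated correlation and fry each called 0 lists in both comparisons, in place of 2 higher and 6 lower for parents and 5 higher and 15 lower for drink. Without a filter, 9 lists were higher and 8 lower for parents, and 5 higher and 20 lower for drink. At a mean CPM of at least 5 these were 4 and 7 for parents, and 5 and 14 for drink. Adipogenic transcription factors were called lower for parents in both settings, and mature adipocyte genes without a filter.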

Other observations

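Scd1, the stearoyl-CoA desaturase, rose with 1,3BD from 162 to 1909 CPM in LnF1 and from 243 to 2369 CPM in ObF1, and Acaca rose by a log2 difference of 1.15, although lipogenesis genes were not called as a list (camera adjusted p = 0.0874, 7 of 18 higher and 3 lower, 9 and 4 adjusted over the list alone). Complement genes were split, with 2 of 10 higher and 7 lower (2 and 7 adjusted over the list alone), and were not called as a list (camera adjusted p = 0.149). Among those that fell was Serping1, the C1 inhibitor, which fell by 2.51 on the log2 scale. The clock genes Per1 (1.36) and Per2 (1.25) rose and Dbp fell by 1.36, in a list of 17 with 5 higher and 1 lower (5 and 1 adjusted over the list alone) that was not called (camera adjusted p = 0.0729). Of 25 DNA and histone methylation enzyme genes, 6 rose, 2 fell and 17 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.149), among them Tet2, an enzyme that oxidises methylated DNA, which rose by 2.11. Of 18 histone deacetylase and sirtuin genes, 1 rose, 6 fell and 11 did not pass (1 and 6 adjusted over the list alone, camera adjusted p = 0.333), among them Hdac5, which fell by 1.78. Dates or times of collection are not given in the labels.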
